A study of Pimephales promelas with 10 samples.

How the data were processed

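Gene expression was measured in pieces of testis of the fathead minnow (Pimephales promelas), a small freshwater fish used in toxicology, kept in culture for 12 h. Per the labels, 4 samples were incubated with progesterone, a steroid hormone, at 1e-06 M and 6 samples were controls. Total RNA of each sample was labelled with Cy3 and hybridised to 1 one-colour Agilent array, so no array held RNA of both groups.

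The deposited scanner files gave each spot's processed signal as a linear fluorescence intensity. Per the file headers, this intensity came from Agilent Feature Extraction 10.7.1.1, which subtracted the background and removed spatial trends within an array but did not normalise between arrays. The files also gave the raw median intensity of each spot and of its local background, and flags for spots that were saturated, non-uniform or well above background, set by Feature Extraction per the file headers. An array held 15744 spots, of which 536 were control spots and 15208 were probes.

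A second source was the authors' value table, on a log2 scale, for the same 10 arrays. Its scale was found by setting each column against the array's own processed signal. The Spearman correlation with the matching array was at least 0.9997 in every column, and with any other array at most 0.986, so the direction was that of the signal and the values were not centred by gene. The column medians were 8.20, 8.20, 8.19 and 8.16 for progesterone samples 5, 8, 7 and 4. They were 8.25, 8.19, 8.20, 8.20, 8.20 and 8.22 for control samples 8, 10, 7, 2, 5 and 4. The method by which the authors normalised these values between arrays is not given in the sources used here.

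For the results given first, log2 of the processed signal was taken and each array's 75th percentile of it was subtracted. Control spots were left out. Probes well above background on at least 4 of the 10 arrays were kept, which left 14096 of the 15208. The 4-array minimum is the size of the smaller group. Progesterone was compared with control on all 10 arrays with lmFit and eBayes of limma 3.58.1 in R 4.3.3, without covariates, with two-sided tests. Adjusted p-values are Benjamini-Hochberg values from limma over the probes kept, with a threshold of 0.05. Intervals of log2 differences are 95% confidence intervals of single probes from the same limma fit. Similarity between arrays was measured by Pearson correlation across probes, which are not independent replicates, and the group difference in it was tested by an exact permutation test over all 210 splits of the arrays into 4 and 6.

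The samples carry numbers in their titles, and numbers 4, 5, 7 and 8 occur in both groups. Whether the numbers pair the samples was checked by correlating, across probes, the deviations of same-numbered samples from their group means. The correlations were 0.574, 0.367, 0.375 and 0.312 for numbers 4, 5, 7 and 8. Between samples of different number in the other group the correlation was at most 0.217. Each of these samples thus correlated most with its same-numbered partner. The lowest same-number correlation was between 0.278 and 0.319 under the other normalisations and filters tried, except normexp with 75th percentile scaling, where it was -0.0483. The pairing therefore comes from the data, since the labels do not say what a number stands for. The comparison was run without a block and again with the number as a block, and the blocked value is printed where it moved a count by over 1.5 times. The labels do not say whether the explants of a group came from separate fish, so the p-values measure the spread between these samples, which can be partly technical.

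The files do not pair the probes with gene names. Probe identifiers named a contig of a sequence assembly for 11862 probes and a sequence record for 3309, and 37 had neither, and 0 of the 15208 matched a RefSeq gene table of the species. The 24 gene lists and cell type markers fixed beforehand, and the rule for naming genes by adjusted p and fold change, rest on gene names, and 0 lists were tested. In their place the 2 probes with the smallest unadjusted p in each direction are given by probe ID, a choice made after the rule proved unusable.

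The fit was tested on simulated data. With no change simulated for independent probes, limma gave 733 probes at an unadjusted p under 0.05 and 0 at an adjusted p under 0.05 among 14096. Known changes were also added to the measured progesterone arrays, in 67 probes per size and with all sizes present together. Of these, 3 of 67 probes changed 2-fold, 40 of 67 changed 4-fold and 58 of 67 changed 8-fold were recovered at an adjusted p under 0.05 without the block. With the number as a block, 0, 40 and 60 of the 67 were recovered. In a second simulation, of independent probes drawn with each probe's mean and residual SD and no shared variation within a number, the fit without the block recovered 10, 50 and 58 of the 67. The blocked fit, which has fewer residual degrees of freedom, there recovered 0, 4 (5.97%) and 32 (47.8%). With many probes changed together the Benjamini-Hochberg cutoff is easier to pass, so these counts can overstate the recovery of a few changed probes.

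The group test, the samples in it, the filter and most alternatives were fixed before the data were examined. The alternatives covered the normalisation, the background correction, the filter on dim probes, the authors' value table, the slide and the number as blocks, array weights, the variance model and leaving out each array. The planned normexp correction was to start from the mean spot signal, which was not used here, and the median spot signal took its place. That substitution, scaling by spike-in controls, fits without certain arrays or probes, fits within slides and combinations with the block were added after the data were seen. The signal of the added viral E1A control RNAs was the mean over 6 spike-ins of the median log2 processed signal of 20 spots each. The arrays lay on 4 slides, and slide was tested as a batch. The number of arrays limits the precision of every value.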

Results

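Signal was obtained from 10 arrays, 4 of progesterone-treated testis explants (numbers 4, 5, 7 and 8) and 6 of controls (numbers 2, 4, 5, 7, 8 and 10). The 75th percentile of the processed signal lay between 1382 and 3927 intensity units. Between 82.6% and 95.2% of the probes were well above background on an array, and 0 probes were saturated on any array. The median signal of negative control spots was at most 4.80 units. Of the 15208 probes, 11935 (78.5%) were well above background on all arrays and 404 (2.66%) on no array. Across the 45 pairs of arrays, the Pearson correlation over probes averaged 0.953, with a range of 0.920 to 0.983. No pair of samples held identical values.

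The comparison the design implies is that of progesterone with control, which asks which testis transcripts change within 12 h of exposure to 1e-06 M progesterone. Progesterone is an intermediate in the synthesis of androgens and other steroids in the testis. No probe differed between the groups by enough to pass the test: with limma and Benjamini-Hochberg adjustment, 0 of 14096 probes passed an adjusted p of 0.05, and the lowest adjusted p was 0.9997. At an unadjusted p under 0.05, limma gave 172 probes, 118 with a higher and 54 with a lower mean in the progesterone group, where an even spread of p-values gives 704.8. Single arrays moved this count, to 388 without control 8 and 103 without progesterone 7 at the extremes, and without control 4 the majority turned, to 125 higher and 142 lower. An ordinary two-sample test without moderation gave 0 probes after adjustment and 201 before it. With the title number as a block, limma gave 0 probes at an adjusted p under 0.05 (lowest 0.9838) and 272 before adjustment, 178 higher and 94 lower.

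**Figure D1:**
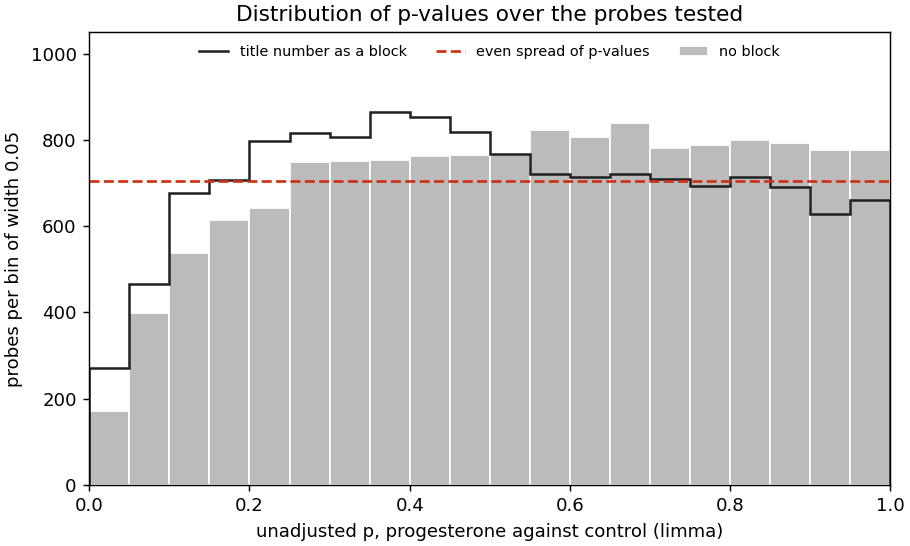
Number of probes (y axis) in each interval of width 0.05 of the unadjusted limma p for progesterone against control (x axis). Grey bars are the fit without a block, the black line is the fit with the title number as a block, and the dashed line at 704.8 probes is an even spread; the lowest interval holds 172 and 272 probes, both below the line.

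The share of higher probes differed between scalings, input signals, filters and variance models. With 75th percentile scaling kept, it was 53.8% of 132 among probes well above background on all arrays and 73.4% of 214 without the filter. A variance trend gave 50.3% of 179 and the ordinary test without moderation 65.2% of 201. In the main fit the share was 68.6% of the 172 with 75th percentile scaling. It was 57.5% of 186 with median scaling, 44.3% of 194 with quantile normalisation and 45.6% of 158 in the authors' value table. With normexp correction of the raw median spot signal, which changes both the input and the background correction, and 75th percentile scaling, it was 6.98% of 86 and the median log2 difference of all probes was -0.35, while normexp with quantile normalisation gave 58.3% of 204 and a median of 0.00938. With scaling to the spike-in controls all 310 were higher and that median was 1.13. By contrast, the median log2 difference was 0.04 with the 75th percentile of the processed signal. Changes are therefore given relative to each array's 75th percentile, and no direction is drawn for the probes as a whole.

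Differences between the groups were measured with moderate precision. The median standard error of a log2 difference was 0.34 (quartiles 0.26 and 0.45), and the median 95% confidence interval reached 0.75 to either side. Taken probe by probe, that interval excluded a 4-fold difference in either direction for 13126 probes (93.1%) and a 2-fold difference for 7353 (52.2%). With the number as a block, the figures were 13646 (96.8%) and 8993 (63.8%). A measured log2 difference above 1 in size was found for 277 probes, none of which passed the adjusted threshold in limma. The groups did not overlap for 34 probes (0.241%), 17 higher and 17 lower with progesterone, where chance gives 0.952% if all 10 arrays are exchangeable. The 15 other splits that part the 4 same-numbered pairs gave a median of 51 such probes (11 to 101), and 11 of the 16 splits gave at least 34 (exact one-sided permutation p = 0.688).

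Since the files do not pair probes with genes, the probes with the smallest unadjusted p in each direction are given by ID. Among those with a higher mean in the progesterone group, UF_Ppr_AF_110073 had a log2 signal of -6.42 ± 0.21 (SD, n = 4) with progesterone and -8.16 ± 0.79 (SD, n = 6) in controls. The log2 difference was 1.74 ± 0.38 (SE) with an unadjusted limma p of 0.000835 and an adjusted p of 0.9997. This probe was well above background on 4 of 4 progesterone arrays but on only 1 of 6 control arrays, so the size of its difference rests mostly on control values near background, and no fold is given. The difference turned to -0.63 after normexp correction with 75th percentile scaling. UF_Ppr_AF_110279 was well above background on all 10 arrays, with -0.19 ± 0.11 (SD, n = 4) against -1.06 ± 0.40 (SD, n = 6). Its log2 difference was 0.87 ± 0.24 (SE; 1.82-fold), with an unadjusted limma p of 0.00409 and an adjusted p of 0.9997. For both probes the 4 progesterone values lay above all 6 control values, so the progesterone sample was necessarily higher in 4 of 4 numbers.

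In the other direction, UF_Ppr_AF_100467 had a log2 signal of -7.26 ± 0.90 (SD, n = 4) with progesterone and -4.39 ± 1.37 (SD, n = 6) in controls. Its log2 difference was -2.87 ± 0.69 (SE), with an unadjusted limma p of 0.00148 and an adjusted p of 0.9997. The groups overlapped, the progesterone sample was lower in 3 of 4 numbers, and the probe was well above background on 2 of 4 progesterone arrays and on 6 of 6 control arrays, so the size of its difference rests partly on values near background. UF_Ppr_AF_109035 was well above background on all arrays and had -5.37 ± 0.41 (SD, n = 4) against -3.60 ± 0.88 (SD, n = 6). Its log2 difference was -1.78 ± 0.44 (SE), with an unadjusted limma p of 0.0018 and an adjusted p of 0.9997. All 4 progesterone values lay below all 6 control values, so the progesterone sample was necessarily lower in 4 of 4 numbers. With the number as a block the log2 differences were 1.94, 0.66, -3.00 and -2.03 in the order given, each with an adjusted limma p of 0.9838.

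**Figure D2:**
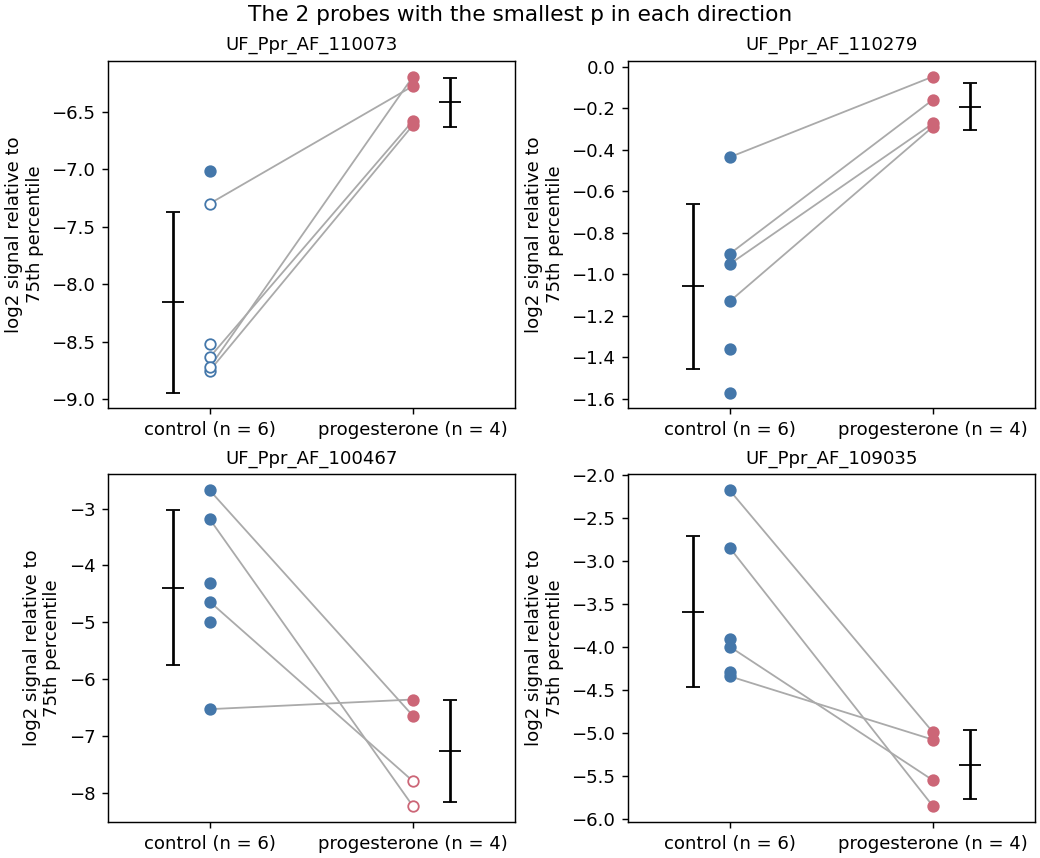
Log2 signal relative to the array's 75th percentile (y axes, a separate range per panel) of the 2 probes with the smallest unadjusted p in each direction, for 6 control and 4 progesterone arrays. Points are arrays (open where the probe was not well above background), grey lines join same-numbered samples, and bars are mean ± SD; of the 4 probes only UF_Ppr_AF_100467 overlapped between the groups.

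Detection was compared as well, since a transcript switched on or off can be missed by a test of means. With progesterone, 3 probes were well above background on all 4 arrays and on no control array. Of the 210 splits of the arrays, 18 gave as many, an exact one-sided permutation p of 0.0857. Among the 16 splits that part the same-numbered pairs, the others gave at most 2, and the exact permutation p of 0.0625 is the smallest they can give. In the opposite direction the count was 0, and other splits gave up to 27. Across all probes, 88.8% to 95.2% were well above background on progesterone arrays and 82.6% to 92.1% on control arrays. These counts can therefore not be told apart from a difference in detection over the whole array.

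Arrays of one group were no more alike than arrays of different groups. The mean correlation within groups was 0.9496 over 21 pairs and between groups 0.9557 over 24 pairs, and 208 of the 210 splits gave a difference as large as the measured -0.00608 (exact one-sided permutation p = 0.99). The between-group mean holds the 4 same-numbered pairs, whose correlations were 0.959 to 0.983. Without them the other 20 between-group pairs averaged 0.9523, so the difference shrank to -0.00274. All 16 splits that part the 4 pairs gave one as large (exact one-sided permutation p = 1, where the smallest possible is 0.0625). The measured difference was thus the lowest of the 16, with or without the same-numbered pairs. The one-sided test asks only whether arrays of one group are more alike, so it does not assess this low end. The first and second principal components held 24.4% and 17.8% of the variation, and single control arrays led both. On the first, control 5 lay at 96.4 (next highest 23.3) and control 8 at -63.0. On the second, control 2 lay at 83.2 (next highest 23.9). The third component, with 16.6%, set both number 4 samples (59.9 and 38.2) apart from both number 7 samples (-55.2 and -42.4). In the 8 arrays whose numbers occur in both groups, the number accounted for 64.8% of the variation with 3 degrees of freedom. Treatment accounted for 7.25% with 1 and the residual for 28.0% with 3. Exchanging treatment within numbers gave as large a treatment share in 7 of 8 sign flips (exact permutation p = 0.875, where the smallest possible is 0.125).

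**Figure D3:**
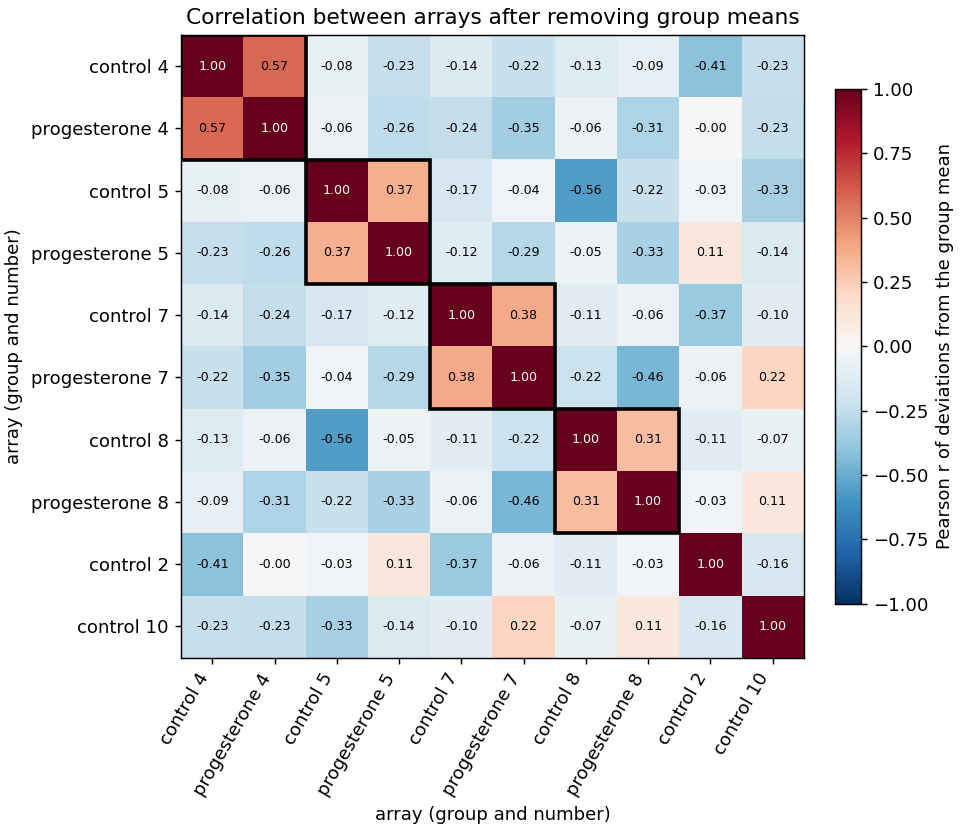
Pearson correlation across probes (colour scale and printed values) between the arrays' deviations from their group means, for the 10 arrays by group and number on both axes. Black squares frame same-numbered samples, whose correlations were 0.574, 0.367, 0.375 and 0.312 for numbers 4, 5, 7 and 8.

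Slides held different mixes of the groups. Slide 1 held progesterone 5 and 8 with control 8, slide 3 held progesterone 4 and 7 with controls 2 and 7, slide 2 held control 10 alone and slide 4 held controls 4 and 5. With slide as a fixed block, limma gave 0 probes at an adjusted p under 0.05 and 420 before adjustment, and with slide as a random block 0 and 172. Within slide 3 the counts were 0 and 323, and within slide 1 they were 0 and 948, the latter resting on 1 control array and 1 residual degree of freedom.

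Control RNA added to each sample gave a measure outside the probes. The E1A spike-in signal lay -0.39 ± 1.67 (SD, n = 6) from the 75th percentile of the probes in controls and -1.48 ± 0.68 (SD, n = 4) with progesterone, on the log2 scale. The difference of -1.09 was within the spread between arrays (two-sided exact permutation p = 0.281). Leaving out single arrays moved it both ways. At the extremes it was -0.55 without control 5 (exact permutation p = 0.405) and -1.53 without control 8 (exact permutation p = 0.0556). Same-numbered samples differed both ways, progesterone minus control being 0.16, -4.20, -0.38 and 0.84 for numbers 4, 5, 7 and 8. The spike-in value was highest in controls 5 (2.33), 2 (0.26) and 10 (-0.26).

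**Figure D4:**
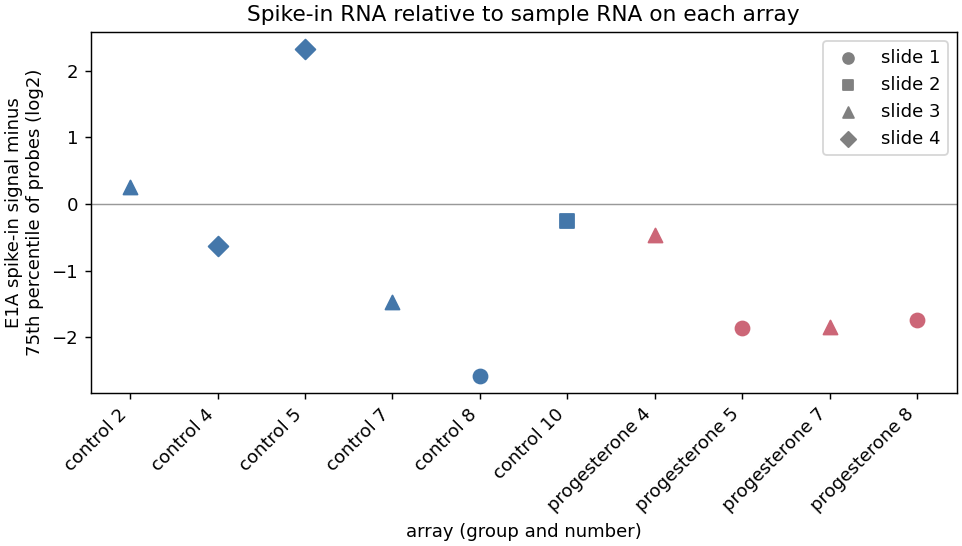
E1A spike-in signal minus the 75th percentile of the probes (y axis, log2) for each array by group and number (x axis), with blue for control, red for progesterone and the marker shape for the slide. Control 5, at 2.33, lies highest and control 8, at -2.59, lowest.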

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

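Of the tests in this part, the one of variation between the numbers was fixed before its result was seen. So were the counts with the number as a fixed or random block and the count without a single array. The others were chosen after. Combinations of group with an array measure or with the signal of a probe named above, 20 in all, were examined for a sample far from the rest. Of these, 2 stood out, both of them array measures, where chance gives about 1 in 20. The 75th percentile of the signal was 1882 for progesterone 4, with a gap to the next progesterone array of 0.83 of the group's range. The spike-in signal relative to that percentile was -0.4617 for progesterone 4, a gap of 0.915 of the range. Both measures share the percentile, so they are not independent.

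The pattern that stands out most is that same-numbered samples deviated together, with a mean correlation of 0.407 against at most 0.181 for the other pairings. Sharing a slide does not account for it, since numbers 4 and 5, whose arrays lay on different slides, had correlations of 0.574 and 0.367, above the highest value of -0.00397 between different numbers on one slide. A chance match is argued against by the mean correlation, the highest of the 24 pairings (exact permutation p = 0.0417, the smallest 24 pairings can give). It stayed highest under each of 9 normalisations and filters, though with normexp and 75th percentile scaling it was 0.227 against 0.21. The 9 use the same arrays, so they are not separate support. Among them, median scaling and spike-in scaling only shift each array by a constant and cannot change a correlation. Of the 24 pairings, 1, the one in the titles, gave as many as the 405 probes that differed between numbers (highest other 57). With spike-in scaling the titled pairing gave 59, which 7 of the 24 reached, and another pairing gave 1348. There the count does not favour the titled pairing. Normexp with 75th percentile scaling gave 0 in limma (375 unadjusted). What a number stands for is open: it may be a fish or a batch of tissue handled together, and the labels do not separate these.

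Fewer probes had an unadjusted p under 0.05 (172) than an even spread gives (704.8). Variation between numbers left in the residual is a candidate explanation: the other 15 splits that part all 4 pairs gave a median of 261 probes, and 89 drawn splits that part fewer pairs gave a median of 618. Control 5, the array least like the others, is not enough to explain it, since 284 probes were found without it. On the 8 paired arrays the count was 103 without the block and 272 with it, and with the number as a random block on all 10 arrays it was 373. These stay below 704.8, and 6 of the 7 other exchanges of treatment within numbers gave at least 272 with the block (median 538, range 175 to 1442), so what remains of the shortfall is not set apart from chance, and no biological explanation was tested for it.

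The spike-in signal was higher on controls 2, 5 and 10 than on the others. These controls were picked from the same values. Relative to the 75th percentile of the probes, control 10 (-0.26) lay close to progesterone 4 (-0.46), while control 5 (2.33) stood apart. Slide alone is argued against, because control 5 exceeded control 4 on the same slide by 2.96 on the log2 scale. Treatment cannot be told apart from spread between samples, with an exact permutation p of 0.281 over 4 against 6 arrays. A different amount of sample RNA or of added control RNA may also be involved and stays untested.

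Splits of the arrays test nothing about the count of 0 probes at an adjusted p under 0.05 by limma, since each of the 100 drawn must give at least 0, and the highest other split gave 55. For the count at an unadjusted p under 0.05 chance could not be excluded: 94 of the 100 splits gave as many as 172, and the highest gave 1970, several times the real count, which may come from a structure of the samples or from probes that vary together. Among the 15 other splits that part all 4 pairs, 10 gave at least 172, with a range of 86 to 722.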

How the results depend on the processing

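Alternatives named here as normexp correction, spike-in scaling, within slides, the 8 paired arrays, without controls 2, 5 and 10, combinations with the block, the similarity without single arrays or same-numbered pairs, the pairings under each normalisation, the spike-in difference without single arrays, and the splits that part the pairs for non-overlap and detection were chosen after the data were seen. The count at an adjusted limma p under 0.05 was 0 in all 32 alternatives, with a lowest adjusted p between 0.08771, without controls 2, 5 and 10 (210 probes before adjustment), and 1. The similarity of arrays kept its direction in every alternative run, and leaving out single arrays gave -0.00877 to -0.00308. Median scaling and spike-in scaling could not change it, since they shift each array by a constant. The count at an unadjusted p under 0.05 (172) moved. It was 86 with normexp correction and 75th percentile scaling, 310 with spike-in scaling, 318 with array weights, 420 with slide as a fixed block, and 948 and 323 within slides 1 and 3. With the number as a replicate block it was 272 (fixed) and 373 (random), with the block 325 in the authors' value table and 338 after quantile normalisation, and without it 103 on the 8 paired arrays. The block changed no call among these counts and the 4 probes named. Leaving out single arrays gave 103 to 388: 388, 351, 284 and 267 without controls 8, 7, 5 and 4, 113 without control 2 and 103 without progesterone 7. The probe UF_Ppr_AF_110073 reversed to -0.63 with normexp correction and 75th percentile scaling and held its direction in 30 of 31 alternatives, with log2 differences up to 2.83 (spike-in scaling) and 0.25 with normexp and quantile normalisation. The other 3 probes kept their direction in all of theirs, over 0.63 to 1.96 for UF_Ppr_AF_110279, -3.30 to -0.77 for UF_Ppr_AF_100467 and -2.04 to -0.69 for UF_Ppr_AF_109035. All 4 probes were picked for the smallest p in these same arrays, so a kept direction is no independent support for a change. The cause of these moves was not tested, though fewer arrays or residual degrees of freedom enter some of them. The alternatives for gene lists, for named genes and for normexp on the mean spot signal were not run, for lack of gene names and of that signal in the columns used. The precision of dim probes is limited by their signal over background.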

Other observations

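Apart from the fit of progesterone with the number as a block, all tests in this part were chosen after the data were seen. Apart from treatment, transcripts differed between the numbers. In the 8 arrays of numbers 4, 5, 7 and 8, with treatment in the model, 405 of 14096 probes differed between numbers at an adjusted p under 0.05 (limma F test with Benjamini-Hochberg adjustment), and 2499 at an unadjusted p under 0.05. For the 405 probes, the range of the mean among the 4 numbers had a median of 3.28 on the log2 scale (9.71-fold), from 1.74 to 10.2. These probes passed the test on the same 8 arrays, so their ranges can be overstated. The filter also let in probes near background on some arrays, where a fold is uncertain. The highest mean was in number 4 for 92 of these probes, in number 5 for 129, in number 7 for 128 and in number 8 for 56. Of the 405, 21 had an unadjusted limma p under 0.05 for progesterone in the same fit, and 0 an adjusted one. Over all 14096 probes that fit gave 272 at an unadjusted limma p under 0.05, a smaller share. Both tests use the same residual variance of a probe, so they are not independent, and no conclusion is drawn from the larger share.

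In the authors' value table, 513 probes differed between numbers, 375 of them shared with the 405. The count depended on the scaling and on the samples. It was 675 with median scaling, 449 with quantile normalisation and 59 with spike-in scaling. With normexp correction and 75th percentile scaling it was 0 in limma, with 375 at an unadjusted p under 0.05, and with normexp and quantile normalisation 341. It was 133 without number 4, 132 without number 7, 300 without number 5 and 354 without number 8.

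For 709 contigs the array carried a pair of probes, one of which had an identifier ending in ms, a tag whose meaning is not given in the sources used here. Of the probes with the tag, 326 (46.0%) were well above background on all arrays, against 543 (76.6%) of their partners, and 78 against 21 were so on no array. For the 241 contigs with both probes well above background on all arrays, the deviations from the group means were correlated over the 10 arrays. The median correlation between the probes of one contig was 0.299, against 0.0276 for randomly matched partners. Without the tagged probes, progesterone gave 0 probes at an adjusted limma p under 0.05 and 158 before adjustment.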
